A study of Mus musculus with 12 samples.

How the data were processed

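RNA of thin slices of outer kidney cortex from male C57BL/6 mice was sequenced after preparation with an Illumina TruSeq RNA kit, per the labels' protocols. Both kidneys of 6 animals gave 12 libraries, 3 animals being wild type (WT 1, 2 and 3) and 3 carrying the HIF2αM3 transgene (17-51, 17-53 and 17-56). Reads were aligned to mouse genome build mm9, per the submitters' processing notes. The aligner, the counting program, the annotation release and whether strand was used in counting are not given in the sources used here.

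The deposited table holds 27412 Ensembl gene IDs. Raw read counts per gene and library were deposited without scaling, per the file headers. The deposited RPKM values were made by the authors after about 1 read had been added to every count, a property read from the values, so that a gene with 0 reads has the RPKM of 1 read. The deposited log2 fold change is the log2 ratio of the mean RPKM of the 6 HIF2aM3 libraries to that of the 6 WT libraries, since recomputing it from the authors' RPKM gave the same values within 8.9e-06. The deposited q-values come from a test on the libraries and a Fisher test, per the file headers, and what entered the Fisher test is not given in the sources used here. These q-values were used only for comparison. Gene symbols were taken from a GENCODE M21 name table, which matched 24630 IDs, and the 2782 others held 1.18% of all counts. That annotation is on another build, so no coordinates are given and it served for names, gene order, overlaps, transcript length and GC content.

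The animal was taken as the replicate because the labels give each animal 2 kidneys. Counts of the 2 kidneys were summed per animal and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors, robust dispersion estimates, a two-sided test and a Benjamini-Hochberg adjusted threshold of 0.05. Standard errors (SE) are the absolute log2 fold change over the square root of the F statistic. Counts scaled to library size with TMM factors are given as CPM, and means ± SD are over 3 animals. Kidney 1 was compared with kidney 2 on the 12 libraries with the animal as a block. The 22 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 1.95, so all were kept as separate libraries.

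Named genes followed a rule fixed before the data were examined. It took Epas1, Hif1a, Arnt and Vhl whatever their values. It took the 10 largest rises and 10 largest falls past the threshold with a symbol, a mean of at least 1 CPM over the 12 libraries and no overlap between the animals of the genotypes. From each list it took up to 4 members past the threshold by adjusted p, or the 1 member with the smallest p where fewer than 2 passed.

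Alternatives covered the replicate unit, the kidney, DESeq2 1.42.0, RLE factors, library size alone, no count filter or a mean of at least 1 CPM, limma on the deposited RPKM with pseudocounts of 0.1 and 5, filters and scaling of RPKM, a fold change minimum, and each animal left out in turn. The settings without the shallowest library, without it and 17-56 kidney 2, with each library left out in turn, with limma on RPKM plus 1, with GC content and transcript length trends removed per animal (lowess span 0.3) and with animals thinned to the shallowest total were added after the data were seen. The planned summing of several rows per gene did not apply, because no symbol had more than 1 row. Library totals ran from 4161829 to 43499743 counts. Intervals of read ratios are exact 95% binomial intervals, which cover counting error only, since PCR reads are not independent molecules.

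The tests were tested on simulated data drawn from the real means and totals with 200 changed genes. Every simulated gene had the same dispersion, about 0.013, genes were drawn independently, and changed genes were taken from those with higher counts. For the genotype comparison, over 19607 simulated genes tested, 100% of genes changed by a log2 fold change of 1 or 2 were recovered, 46% of those changed by 0.5 and 2% of those changed by 0.25. For the kidney comparison, over 18904 genes, the shares were 100% at 1 and 2, 82% at 0.5 and 10% at 0.25. Genes simulated without a change made up 2 calls, or 1.59% of all calls, in the genotype comparison and 11 calls, or 7.01%, in the kidney comparison. A list shifted by 0.3 was called and 0 of 20 unshifted lists were. The shares recovered do not hold for genes that vary more between animals, such as Pck1 (log2 fold change -1.52, edgeR adjusted p = 0.0807). The simulated lists had no correlation between genes, so they do not show how camera fares with correlated genes.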

Results

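The kidney cortex transcriptome was measured in mice that carry a HIF2αM3 transgene under a γ-glutamyl transferase (GGT) promoter, which is active in the proximal tubule, and in wild-type mice. HIF2α, encoded by Epas1, is a transcription factor of the hypoxia response, and the comparison asks how cortical gene expression differs in mice with the transgene. The names of all 3 HIF2aM3 animals share the prefix 17, which no WT animal has. Whether it marks 1 transgenic line is not given in the sources used here. If so, line, insertion site and background cannot be told apart from the action of the transgene. Each genotype had 3 animals with 2 kidneys each. Library totals ran from 24032148 to 43499743 counts, except for kidney 2 of HIF2aM3 17-51 with 4161829, called the shallow library here. Summed per animal, totals were 51309463, 65101936 and 66566563 counts for WT 1, 2 and 3 and 32392033, 85018818 and 56475079 for HIF2aM3 17-51, 17-53 and 17-56.

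**Figure D1:**
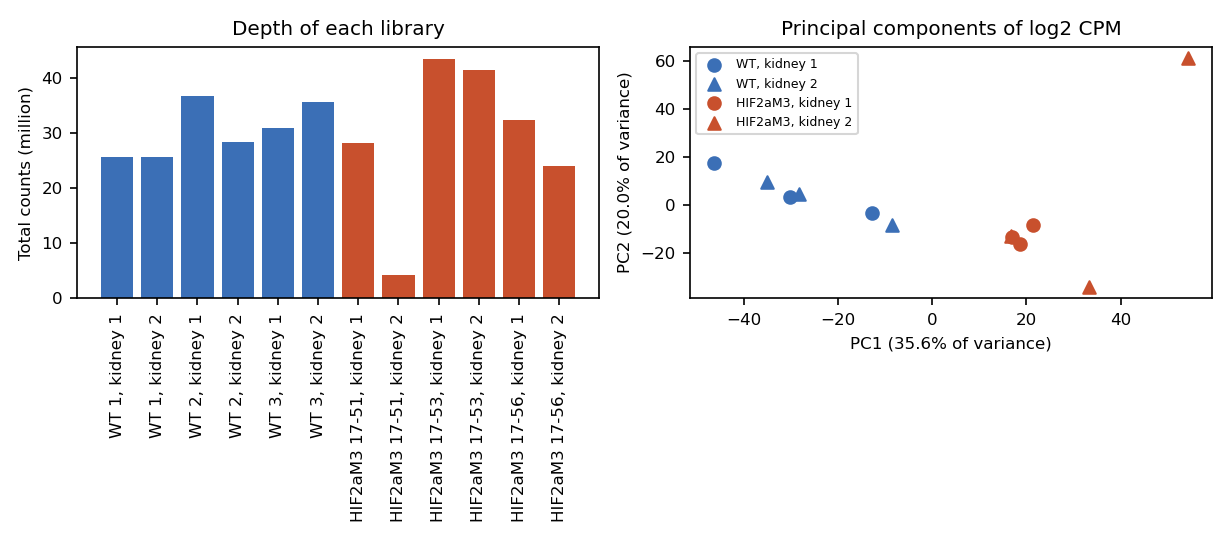
Left, total counts of each of the 12 libraries. Right, the first and second principal components of log2 CPM, with 35.6% and 20.02% of the variance, colored by genotype and shaped by kidney number. The 17-51 kidney 2 library is the shallowest and lies apart from all others on the second component (61.1), and 17-56 kidney 2 lies at the opposite end (-34.0).

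Epas1 was at 204 ± 30.9 CPM (SD, n = 3) in WT and 267 ± 16.7 CPM in HIF2aM3 animals, a log2 fold change of 0.39 ± 0.11 (SE) that did not pass the threshold (edgeR adjusted p = 0.0881). Its libraries ran from 169.7 to 246.9 CPM in WT and from 243.4 to 287.0 CPM in HIF2aM3. The labels do not say whether reads of the transgene can be counted under Epas1. Hif1a, Arnt and Vhl, which encode the other main α subunit, the shared partner subunit and the ubiquitin ligase component that marks HIFα for degradation, had log2 fold changes of -0.05 ± 0.06, 0.09 ± 0.05 and -0.06 ± 0.07 (SE). None of the 4 passed the threshold.

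The largest rises in the HIF2aM3 cortex were in genes with low values in WT, Apoa4 having the highest WT mean of the 10. Muc2, which encodes a secreted mucin of the gut, rose from 0.112 ± 0.078 to 18.0 ± 9.83 CPM (SD, n = 3), and Apoa4, an apolipoprotein gene of intestine and liver, from 1.34 ± 0.861 to 46.4 ± 18.3 CPM. A2m, which encodes the protease inhibitor α2-macroglobulin, rose by a log2 fold change of 5.89 ± 0.36 (SE). Among the falls, Gpt, which encodes alanine aminotransferase, dropped from 49.2 ± 5.53 to 23.2 ± 2.17 CPM, and Fkbp5, a glucocorticoid-responsive co-chaperone gene, from 159 ± 31.5 to 73.9 ± 10.02 CPM. Of 19564 genes tested, 733 differed, 377 higher and 356 lower in HIF2aM3, and 145 of them by an absolute log2 fold change of at least 1. Which direction held more calls depended on the filter, with 439 higher and 564 lower with no filter and 343 higher and 401 lower at a mean of at least 1 CPM. Library size alone gave 376 higher and 249 lower.

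The other large rises were Defb19, a β-defensin gene (5.23 ± 0.40, SE), Gm10680 (5.2 ± 0.50), Cpne5 (4.61 ± 0.59) and Synpr (4.47 ± 0.64), with adjusted p between 0.00911 and 0.0265. Lactbl1 had 3 reads in the WT animals and 1691 in HIF2aM3, a ratio of depth-scaled reads of 584 (95% counting interval 199.6 to 2837). F2, which encodes prothrombin, had 4 and 563 reads, a ratio of 146 (56.7 to 538), and the homeobox gene Gbx2 had 4 and 501 reads, a ratio of 129.9 (50.4 to 479). Without kidney 2 of WT 3 the ratio was 1420 for Lactbl1 (254.5 to 56120) and 210.4 for Gbx2 (57.9 to 1742). The F2 ratio was 487.5 (87.1 to 19290) without kidney 1 of WT 3 and 86.8 (33.5 to 321) without kidney 1 of 17-53, which had 7.07 CPM against 1.08 CPM in kidney 2 of that animal. Kidney 1 of 17-53 was also above its kidney 2 for A2m (15.1 against 6.33 CPM), Apoa4 (88.2 against 35.6 CPM) and Gm10680 (44.9 against 17.2 CPM). Muc2 (18.2 against 18.8 CPM), Lactbl1, Gbx2 and Synpr were not higher in it, and Defb19 (47.2 against 46.5 CPM) and Cpne5 (4.22 against 3.28 CPM) differed less. In the GRCm38 annotation Gm10680 and Apoa4 overlap in exons on opposite strands, as do Gbx2 and D130058E05Rik and, among the falls, Nefl and Nefm. Without a stated strand setting, reads within such pairs cannot be told apart. Cpne5, Acnat2, Hadha, Ftl1, Ankrd37, Irs2, Pfkp, Gys1, Csf1r, Krt7 and Avpr2 also overlap a gene on the opposite strand, and Ftl1 another on the same strand, so their values are uncertain too.

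Nat8f5, of a family of N-acetyltransferase genes, had the largest fall by log2 fold change (-1.65 ± 0.18, SE), from 60.6 ± 13 to 19.2 ± 3.13 CPM. It overlaps in exons with its family member Nat8f6 on the same strand, so its value is uncertain. Kcnh1 (-1.64 ± 0.34), Nefl (-1.43 ± 0.24), Zfp648 (-1.40 ± 0.20), Slc16a14 (-1.22 ± 0.23), Lrp12 (-1.14 ± 0.20), Acnat2 (-1.01 ± 0.11) and Foxi1 (-1.01 ± 0.19), the last a transcription factor gene of intercalated cells, completed the 10 largest falls. All 733 called genes had no overlap between the 3 animals of one genotype and the 3 of the other. Among all tested genes 6254, or 31.97%, were separated in this way, where chance gives 10%.

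**Figure D2:**
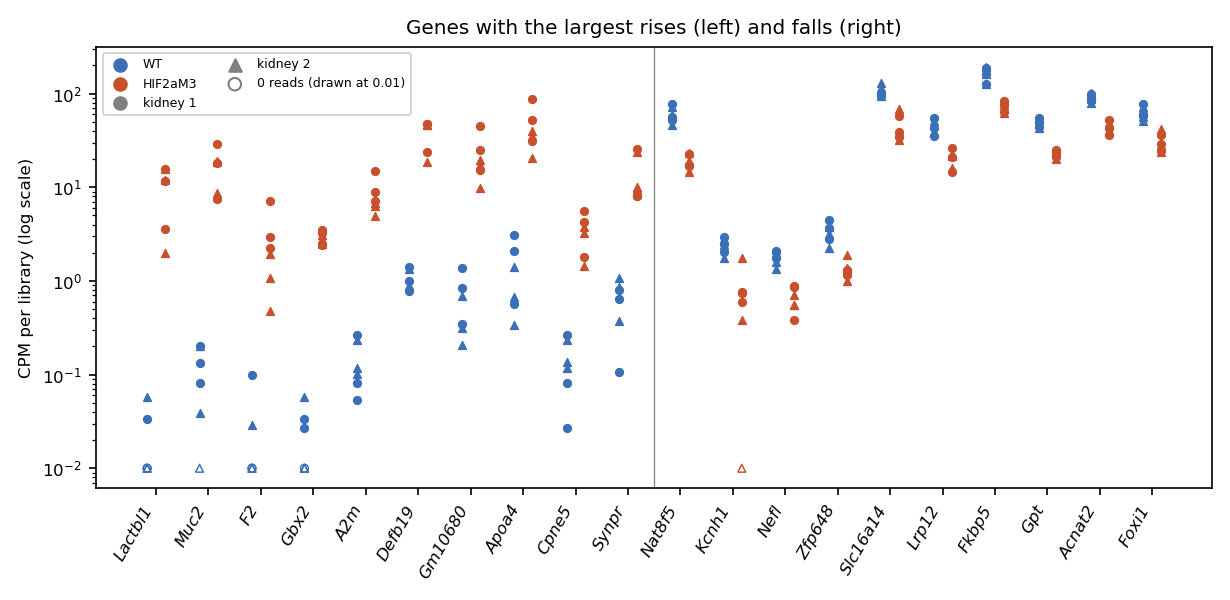
CPM of each library, on a log axis, for the 10 largest rises and 10 largest falls, with WT and HIF2aM3 in separate colors and kidney numbers as shapes. Open symbols stand for libraries with 0 reads. Muc2 averages 0.112 CPM in WT and 18.0 CPM in HIF2aM3 animals.

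The call count rested on the replicate unit and on single animals. Leaving out 1 animal at a time gave 42 calls without 17-51, 11 without 17-53, 196 without 17-56, 115 without WT 1, 1549 without WT 2 and 187 without WT 3, and treating the 12 libraries as replicates gave 4829. Gbx2, Defb19 and A2m kept their call in all 6 of these leave-outs. The count was 480 without kidney 2 of WT 1, 479 without kidney 1 of 17-56, 632 without the shallow library, 597 without it and 17-56 kidney 2, and 476 after removal of GC content and transcript length trends.

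Genes of the hypoxia response moved in part. Of 36 tested HIF target genes 5 rose, none fell and 31 did not pass. When adjusted over the list alone 7 were called, 6 higher and 1 lower, the last being P4ha2 (log2 fold change -0.28 ± 0.07, SE), a prolyl 4-hydroxylase subunit gene named after its values were seen. Ankrd37 rose by a log2 fold change of 2.22 ± 0.25 (SE), while its overlapping neighbor Lrp2bp, chosen after its values were seen, rose by 1.93 ± 0.36, and reads of the pair cannot be told apart. Hk2, which encodes hexokinase 2, rose by 1.64 ± 0.31, Bnip3l, a mitophagy receptor gene, by 0.47 ± 0.06, and Kdm3a, a histone demethylase gene, by 0.38 ± 0.06. Hk2 had few reads, 74 in the WT animals and 222 in HIF2aM3. Its value in kidney 1 of 17-56, 0.506 CPM, lay inside the WT library range of 0.202 to 0.786 CPM. Hk2 and Kdm3a each kept their call in 1 of the 6 leave-outs of an animal. Of 17 tested genes reported to depend mainly on HIF2, 2 rose and none fell, namely Egln3, which encodes a HIF prolyl hydroxylase (1.83 ± 0.35), and Irs2, an insulin receptor substrate gene (0.85 ± 0.09), and 4 were called over the list alone. Camera called both lists higher, at adjusted p = 0.0128 and 0.00309. With an estimated correlation the adjusted p = 0.57 and 0.262, and the call of the first list was lost without WT 2 (adjusted p = 0.0946) and without 17-51 (adjusted p = 0.0529).

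Of 28 tested genes of fatty acid oxidation 7 fell, none rose and 21 did not pass, and 17 were called when adjusted over the list alone. Camera called the list lower at adjusted p = 2.42e-10, and with an estimated correlation the adjusted p = 0.262. Hadha, the α subunit gene of the mitochondrial trifunctional protein, fell from 206 ± 9.59 to 156 ± 4.07 CPM (SD, n = 3). Cpt2 and Slc25a20, of the carnitine shuttle, had log2 fold changes of -0.51 ± 0.09 and -0.42 ± 0.07 (SE), and Eci1, an enoyl-CoA isomerase gene, of -0.54 ± 0.09. Nuclear-coded oxidative phosphorylation genes had negative values for all 40 tested members, of which 2 fell, Ndufa8 (-0.31 ± 0.05) and Ndufb10 (-0.31 ± 0.05), both complex I subunit genes, and 13 were called over the list alone. The list medians were -0.24 and -0.14. Camera called the second list lower at adjusted p = 4.12e-07, and with an estimated correlation the adjusted p = 0.602.

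Of 15 collecting duct genes 5 fell, none rose and 10 did not pass. Camera called the list lower at adjusted p = 2.71e-08, and with an estimated correlation the adjusted p = 0.349. Scnn1a, the α subunit gene of the epithelial sodium channel, fell from 190 ± 10.4 to 108 ± 13.8 CPM (SD, n = 3). Krt7, Avpr2, which encodes the vasopressin receptor, and Foxi1 had log2 fold changes of -0.54 ± 0.09, -0.31 ± 0.06 and -1.01 ± 0.19 (SE). Of 17 genes of the loop of Henle and distal convoluted tubule 2 fell, Kcnj10, a potassium channel gene (-0.50 ± 0.08), and Klk1, which encodes kallikrein (-0.70 ± 0.14), and 15 did not pass, with camera lower at adjusted p = 0.000645 and with an estimated correlation at adjusted p = 0.57. Of 15 endothelial genes 3 rose, Kdr, the VEGF receptor gene (0.70 ± 0.12), the transcription factor gene Erg (0.62 ± 0.12) and Emcn (0.57 ± 0.12), and 12 did not pass, with camera higher at adjusted p = 2.41e-06 and with an estimated correlation at adjusted p = 0.57. Over the lists alone 9, 4 and 9 were called.

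Of 20 genes of extracellular matrix and fibroblasts none was called alone, while camera called the list higher at adjusted p = 0.000176 (0.57 as adjusted p with an estimated correlation), and its member with the smallest p, Pdgfrb, had a log2 fold change of 0.51 ± 0.14. Of 20 leukocyte genes 1 rose, the macrophage receptor gene Csf1r (0.58 ± 0.10), with camera at adjusted p = 0.0128 and with an estimated correlation at adjusted p = 0.904. The leukocyte call was lost without WT 1 (adjusted p = 0.445), without 17-56 (adjusted p = 0.172) and without the shallow library and 17-56 kidney 2 (adjusted p = 0.139).

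**Figure D3:**
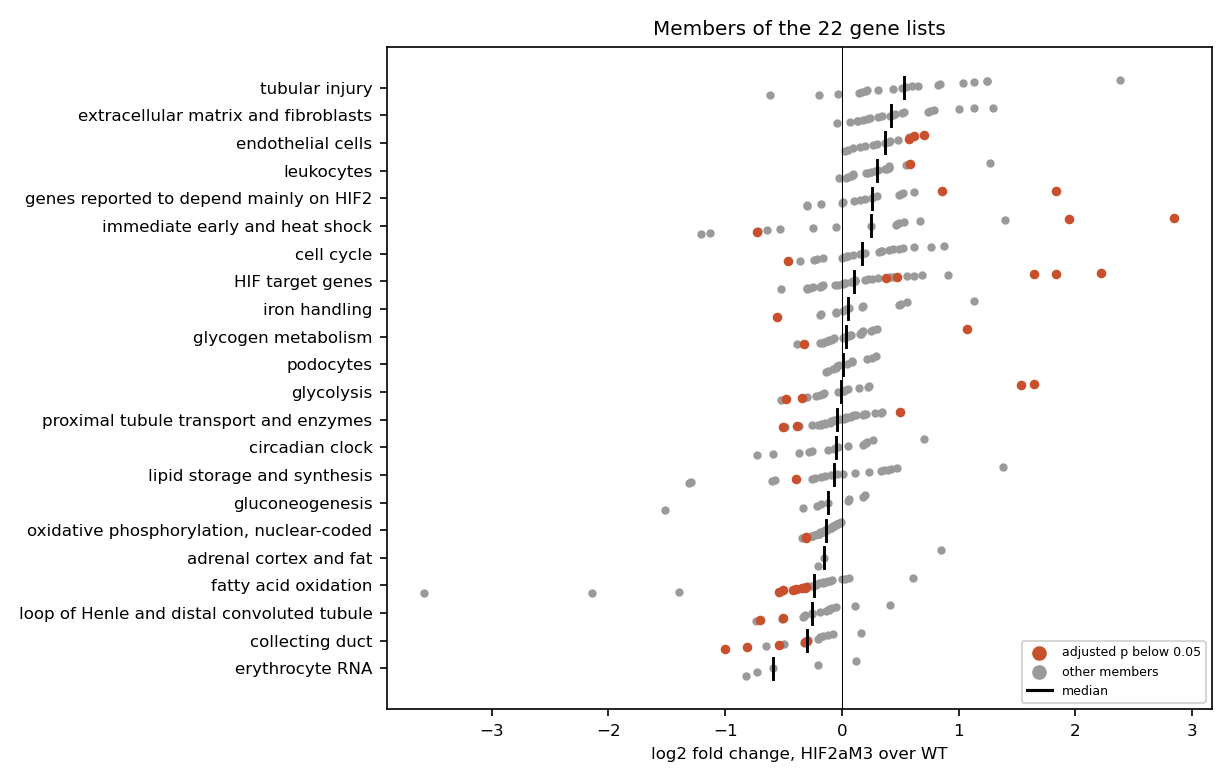
Log2 fold change (HIF2aM3 over WT) of each tested member of the 22 gene lists, one list per row ordered by median. Colored points passed adjusted p of 0.05 and black bars are medians, which run from -0.59 for erythrocyte RNA to 0.53 for tubular injury (-0.11 without 17-56). The oxidative phosphorylation points all lie below 0.

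Carbohydrate genes split by member. In glycolysis Pfkp, a phosphofructokinase gene (1.53 ± 0.18, SE), and Hk2 rose, and Eno1 (-0.48 ± 0.09) and Pgam1 (-0.35 ± 0.07), of its lower part, fell, with 14 of 18 not passing and no list call (camera adjusted p = 0.758). In glycogen metabolism Ppp1r3b, a glycogen-targeting phosphatase subunit gene, rose (1.07 ± 0.14) and Gys1, which encodes glycogen synthase, fell (-0.33 ± 0.05), with 25 of 27 not passing (camera adjusted p = 0.717). Camera looks for a shift of a list in 1 direction. Fry without direction gave adjusted p = 0.0005 for glycolysis and 9.94e-05 for glycogen metabolism. It asks whether any members differ and does not compare them with other genes. In gluconeogenesis none of 9 passed. Pck1, which encodes its cytosolic rate-controlling enzyme, had 1907 ± 757 CPM (SD, n = 3) in WT and 667 ± 307 CPM in HIF2aM3 (adjusted p = 0.0807, list adjusted p = 0.262).

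In the proximal tubule list 32 of 35 genes did not pass. Slc5a12, a lactate transporter gene, rose (0.49 ± 0.10, SE), and Slc22a6, which encodes the organic anion transporter OAT1, and Amn, a part of the cubilin receptor complex, fell (-0.50 ± 0.11 and -0.38 ± 0.08), with camera at adjusted p = 0.475. The immediate early genes Egr1 (2.85 ± 0.32) and Fos (1.94 ± 0.37) rose, and the heat shock gene Hsph1 fell (-0.73 ± 0.12), with 14 of 17 not passing (camera adjusted p = 0.758). Fos was at 12.1 CPM in kidney 2 of 17-56 and 0.727 CPM in kidney 1, inside the WT range of 0.634 to 1.45 CPM. Its call was lost in all 6 leave-outs of an animal and also without kidney 2 of 17-56 (log2 fold change 1.2), kidney 1 of 17-56 (2.5) or kidney 1 of WT 2 (1.90). Egr1 kept its call in 3 of the 6 and lost it without kidney 2 of 17-56 (2.65). Single members fell in iron handling (Ftl1, ferritin light chain, -0.56 ± 0.07), lipid storage and synthesis (Dgat2, -0.39 ± 0.06) and the cell cycle (Tyms, -0.46 ± 0.09), whose camera adjusted p = 0.975, 0.475 and 0.52. Fry without direction gave these lists adjusted p = 3.12e-06, 0.005065 and 0.2675. It gave adjusted p = 0.005065 for the proximal tubule list and 0.003065 for the immediate early and heat shock list.

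No member passed in the remaining lists. The members with the smallest p were Clu in tubular injury (-0.62 ± 0.13, SE), Slc25a37 in erythrocyte RNA (-0.21 ± 0.05), Magi2 in podocytes (0.29 ± 0.08), Per2 in the circadian clock (-0.73 ± 0.28) and Car3 in adrenal cortex and fat (0.85 ± 0.40). Camera gave adjusted p = 0.181, 0.06, 0.714, 0.969 and 0.975 for these lists. Only 3 of the 12 members fixed for adrenal cortex and fat, and 5 of 8 for erythrocyte RNA, were measured well enough to test. Of the lists without a call, the median changed sign in 1 of 5 other scalings or units for cell cycle, circadian clock, podocytes and proximal tubule, in 2 for adrenal cortex and fat and in 3 for glycolysis. It also changed sign without 17-56 for tubular injury (-0.11), immediate early genes (-0.05), iron handling (-0.02), podocytes (-0.02), glycolysis (0.02) and proximal tubule (0.02), and without WT 2 for glycogen metabolism (-0.005). Further changes of sign came without WT 1 for iron handling (-0.02), with a filter of 1 CPM for adrenal cortex and fat (0.35), and with no filter and without WT 1, WT 3 or 17-53 for podocytes. Without the shallow library and 17-56 kidney 2 it changed for tubular injury (-0.02), immediate early genes (-0.17) and podocytes (-0.05). The medians of the 9 called lists kept their sign in all of these settings. The glycolysis median was -0.01 with a mean of 0.08, the iron handling median was 0.05 with camera pointing lower, and the adrenal cortex and fat median was -0.15 with a mean of 0.17.

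Between the 2 kidneys of an animal few genes differed. With the animal as a block, 17 of 19034 genes were called, 2 higher and 15 lower in kidney 2. Hbb-bt, a β-globin gene with a near-identical copy and so an uncertain value, was higher in kidney 2 (log2 fold change 0.47 ± 0.07, edgeR adjusted p = 0.0103), and the apolipoprotein gene Apoc3 (-0.34 ± 0.05, adjusted p = 0.0103) and Hsd17b2, which encodes a steroid dehydrogenase (-0.43 ± 0.07, adjusted p = 0.0107), were lower, each in all 6 animals (± SE), these 3 being chosen after their values were seen. The labels do not say which side a number stands for. Without the animal of the shallow library 10 genes were called, and with no animal block 0, with 188 at an unadjusted p under 0.05. A test of whether the kidney difference itself depended on genotype called 0 genes in edgeR, with 588 at an unadjusted p under 0.05.

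Kidneys of the same animal had a higher median correlation than different animals of one genotype, a difference that was not tested. The median Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.993 for the 6 pairs from one animal, 0.988 for the 24 pairs of different animals of one genotype and 0.982 for the 36 pairs of different genotypes. Over 8347 genes with a mean of at least 500 reads, the median SD was 0.0671 log2 units between the kidneys of an animal and 0.0823 between animal means. The first is an SD of single libraries and the second of means over 2 kidneys. Averaging lowers the second, so the values are not like for like.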

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

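The tests of liver tissue and of the proximal tubule share were chosen only after the results were seen. Of 134 sets of 6 libraries examined, 6 held a library far from the others, and chance gives about 1 in 20 where the 6 values are independent. The kidneys of an animal are correlated (consensus correlation 0.407), so that rate does not hold here and no comparison with chance is drawn. In HIF2aM3, kidney 2 of 17-56 was the highest library for Clu (438 CPM, median 275 CPM), Pdgfrb (90.1 CPM, median 70.8 CPM) and Fos (12.1 CPM, median 2.45 CPM). The shallow library, kidney 2 of 17-51, was the highest for Kdm3a (43.9 CPM, median 38.5 CPM) and Erg (16.7 CPM, median 12.6 CPM). In WT, kidney 1 of animal 3 was the highest for F2, at 0.1002 CPM with a median of 0.

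The deposited log2 fold changes of low-count genes lean towards HIF2aM3. Their median was 0.83 over 5171 genes with a mean under 1 read and 0.02 over 5415 genes with at least 1000 reads. The authors' added read weighs most in the shallow library, and without that library the median of the low-count genes was -0.0322, which is what this explanation needs. A real rise of these genes stays open, since their pooled depth-scaled reads were 1.13 times as high in HIF2aM3 (95% interval over animals 1.06 to 1.21). That interval resamples only 3 animals per genotype, so it is likely too narrow.

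Muc2, Apoa4, F2, A2m and the other largest rises include genes best known from liver and intestine. Liver tissue in the HIF2aM3 samples is argued against by a median log2 fold change of -0.52 over the 12 tested of 20 liver-abundant genes, 9 of which the WT cortex also expresses at 1 CPM or more, and by Alb at 8.2 ± 0.364 CPM (SD, n = 3) in WT and 8.24 ± 3.01 CPM in HIF2aM3. For intestinal tissue, the median was -0.12 over the 3 tested of 17 intestine-abundant genes, of which 10 were in the table and the rest had no value. That median is the value of Vil1, already at 206 CPM in the WT cortex, so it says little. The untested ones among those 10 together reached 0.223 CPM in HIF2aM3, which argues against intestinal tissue for the genes it covers. After all animals were thinned to the shallowest the smallest rise of the 10 was 4.34. Random thinning keeps the expected share of reads of each gene, so this result cannot decide on depth. F2, A2m and Apoa4 were higher in kidney 1 of 17-53 than in its kidney 2, though kidney 2 also lay above every WT library for each. The liver and intestine values sum both kidneys, so they do not settle that library alone. Expression from the cortex of HIF2aM3 mice remains a hypothesis, found and tested on the same animals.

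Fatty acid oxidation and oxidative phosphorylation genes were lower in HIF2aM3 while log2 fold changes fell with GC content (Spearman -0.303 across 15300 genes, which are not independent). With that trend and the length trend subtracted, the list medians were -0.20 (95% bootstrap interval over genes -0.35 to -0.15) and -0.11 (-0.16 to -0.06), so the trend is not the whole cause of either, though the second lay under its preset bound of -0.10 by less than its interval. A lower share of proximal tubule cells would lower that list by about as much, yet the medians of the lists lay below the proximal tubule median by -0.20 (-0.36 to -0.10) and -0.10 (-0.21 to -0.02). These intervals are over genes and leave out the spread between animals. The comparison covers the proximal tubule share alone. The promoter of the transgene is active in that segment, so its list may not track the share of cells alone. The medians of the collecting duct and loop of Henle lists were -0.30 and -0.26, and that of the endothelial list was 0.37. A change in the shares of other cell types was not tested and stays open. A genotype effect on these genes stays open as a hypothesis.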

How the results depend on the processing

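The tests without the shallow library, without 17-56 kidney 2, with 1 library left out at a time, with limma on RPKM plus 1, with trends removed and with thinning were chosen after seeing the data. The count of 733 genes called between the genotypes was within 1.5 times of its value with RLE factors, library size alone, either other count filter, kidney 1 alone, the shallow library left out, that library and 17-56 kidney 2 left out, and thinned animals. It rose to 4829 with 12 libraries as replicates, 4697 with the kidney number added, 4428 without the shallow library among them, 2795 with the animal as a random effect and 2058 with DESeq2. It fell to 337 with kidney 2 alone, 476 with GC and length trends removed and 145 with a minimum log2 fold change of 1. On the deposited RPKM, limma called 97 with a pseudocount of 1, 110 with 0.1, 63 with 5, 7 with no filter, 306 with a mean of at least 5, 185 with median-ratio scaling and 54 without trend and robust options. Median-ratio scaling raised the higher calls from 50 to 62 and the lower calls from 47 to 123, which moved the share of higher calls from 51.6% to 33.5%. Leaving out 1 animal gave 11 to 1549 calls, with fewer samples in each fit, and leaving out 1 library gave 479 to 1078. The cause of the other changes was not tested.

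The kidney comparison gave 0 calls with no animal block, 62 with no filter and 10 without the animal of the shallow library, against 17. The correlation between kidneys of an animal moved by less than its spread with Spearman correlation and without the shallow library.

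Of the 9 lists called by camera, 0 were called with an estimated correlation and 2 by directional fry, fatty acid oxidation and HIF2-dependent genes. With an estimated correlation the adjusted p was 0.262 for both of these, 0.349 for collecting duct, 0.57 for HIF targets, endothelium, matrix and loop of Henle, 0.602 for oxidative phosphorylation and 0.904 for leukocytes. With directional fry it was 0.0603 for collecting duct, 0.178 for HIF targets and oxidative phosphorylation, 0.187 for endothelium and loop of Henle, 0.202 for matrix and 0.522 for leukocytes. The leukocyte list was also lost without the shallow library and 17-56 kidney 2 (adjusted p = 0.139). Erythrocyte RNA was called with no filter (adjusted p = 0.0196) and with trends removed (adjusted p = 0.0239). Leaving out 1 animal gave adjusted p from 3.54e-06 to 0.0946 for HIF targets, 6.27e-10 to 0.445 for leukocytes, 8.77e-06 to 0.991 for the cell cycle, 0.000535 to 0.262 for erythrocyte RNA and 0.00267 to 0.477 for tubular injury. The other lists kept their side of the threshold in all leave-outs.

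Of 55 called named genes, none changed sign in 2088 pairs of gene and setting, and the call was lost in 578. With 1 library left out at a time 37 kept it in all 12 fits. Without 17-53, 51 lost it, without 17-51 44, WT 1 42, 17-56 32, WT 3 31 and WT 2 5. Among the uncalled named genes the sign changed in 1 pair and 52 pairs were called. Depth limits the genes with few WT reads, such as Lactbl1 with 3.
No paired analysis was possible because the genotypes share no replicate numbers.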

Other observations

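Other gene groups were listed only after some of their members had been seen, and apart from the count of neighbouring pairs the tests in this part were chosen after the results were seen. Of 18 tested chaperone and stress genes of the endoplasmic reticulum 4 fell and none rose, namely Creld2 (log2 fold change -0.86 ± 0.06, SE), Manf (-0.70 ± 0.07), Hyou1 (-0.60 ± 0.09) and Hspa5, which encodes the chaperone BiP (-0.51 ± 0.09), and camera gave adjusted p = 2.41e-07 (with an estimated correlation adjusted p = 0.0749). Manf overlaps in exons with Rbm15b on the same strand and Dcaf1 on the opposite one, so its value is uncertain. Ren1, the renin gene, fell from 98.9 ± 6.44 to 58.3 ± 7.09 CPM (SD, n = 3), while the other 5 tested members of the juxtaglomerular list did not pass (list adjusted p = 0.38, with a median of 0.10 and camera pointing lower). Of 14 glucocorticoid-induced genes 1, Fkbp5, fell, while 8 were called when adjusted over the list alone, 3 of them higher, with camera lower at adjusted p = 0.0236 and with an estimated correlation at adjusted p = 0.342.

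Immunoglobulin and plasma cell genes had higher values in HIF2aM3 with a wide spread between animals. None of 12 tested passed over all genes, 5 were called when adjusted over the list alone, and camera gave adjusted p = 5.22e-06 (with an estimated correlation adjusted p = 0.246). Igkc was at 130.5 ± 106 CPM (SD, n = 3) in WT and 394 ± 159 CPM in HIF2aM3, and Jchain at 45.9 ± 41.1 and 175 ± 71.9 CPM. The liver-abundant list was lower by camera (adjusted p = 0.00674, with an estimated correlation adjusted p = 0.25) and the intestine-abundant list was not called (adjusted p = 0.19). Genes outside the naming rule, chosen after their values were seen, included Susd5, with the smallest adjusted p of all (log2 fold change 3.25 ± 0.13, SE, adjusted p = 0.000257), Apoc3 (4.12 ± 0.26) and Hsd11b1, which encodes a glucocorticoid-activating enzyme (1.97 ± 0.16).

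In the authors' deposited table, 3445 genes had a q-value under 0.05 in the test on libraries, 2015 higher and 1430 lower in HIF2aM3, and 11301 in the Fisher test. Of the 733 genes called per animal, 721 were among the 3445, with the same direction for all 721.

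Called genes lay next to one another on chromosomes more often than in random draws. Outside named families 60 neighbouring pairs were both called, against 25.2 on average with 35 as the upper end of the 95% range of 10000 random draws (p = 0.0001 by permutation, the smallest they can give), and 55 of the 60 moved in one direction. Reads shared between overlapping genes are not the whole cause, since 39 pairs had no overlap in span (upper end 30), but they stay open for the 21 pairs with overlapping exons (3.18 on average, upper end 7), all 21 of which moved in one direction, while 0 pairs overlapped in span alone (1.14 on average). A single segment or insertion site does not either, since the pairs lay on 19 chromosomes and 53 lay outside chromosome 1, which had the most (upper end 33). Several segments of another origin or position effects may contribute and were not told apart from shared local regulation. The random draws were not matched on GC content or expression, so the trend with GC content was not told apart either. Families were told by symbol, so the ferritin gene Ftl1 and its copy Ftl1-ps1 each gave a pair with an overlapping gene.

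The 6 animals can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real split called 733 genes and the highest of the others 0, and 1 of the 10 splits reached the real count. Of 32 assignments of the kidney numbers within animals, 1, the real one, reached its own count of 17, the highest others being 13 and 12. That is the smallest share that 32 assignments can give, and the rule was set after the results were seen. Chance is therefore not excluded for that comparison.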
